A study of Mus musculus with 23 samples.

How the data were processed

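Total RNA was extracted with TRIzol from the whole hippocampus of 23 male C57BL/6JNIA mice, labelled with biotin and hybridised to 1-colour Affymetrix arrays of 12488 probe sets, per the labels' protocols. The labels call each sample a biological replicate and name no technical replicates. The mice had been trained in the Morris water maze and were killed by cervical dislocation, per the labels' protocols, and no batch, scan date, pairing or time of killing was given in the sources used here. The running numbers in the sample titles do not overlap between the ages. If samples were handled in that order, its effect cannot be told apart from that of age. Groups were taken from the age in the labels, 15 months for 14 mice and 2 months for 9. Replicate numbers only name the mice within an age and pair none of them.

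The deposited values are intensities on a linear scale, 1 signal per probe set and array, made with MAS5 per the submitters' processing notes. The version and settings are not given in the sources used here. The mean of an array's signals after trimming 2% of the values at each end was 500.3 on every array to 1 decimal, which shows that the arrays had been scaled alike before deposit, so the values were used without further normalisation. Scanner files and detection calls were not used here. No pair of arrays held the same values: at most 44 of the 12488 values were identical between 2 arrays, and the lowest SD of the log2 difference of a pair was 0.28.

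Probe sets were named through the platform annotation. Of 12422 non-control probe sets 10833 had 1 gene symbol, 396 several and 1193 none. Over the whole platform annotation, 10839 entries with 1 symbol had an Entrez identifier in the RefSeq table of the assembly GRCm38.p6, with 0 symbols updated. A probe set with several symbols is described by its values, without a gene name. No coordinates are given, since the array files name no genome build. The 66 control probe sets were left out of the main test.

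The signals were analysed as log2(signal + 16), so that a fold change is on that scale and understates the change of dim genes. Probe sets were tested if their mean log2 value over all arrays was above the 40th percentile of the non-control probe sets, a signal of 91.7, which left 7453, of which 6756 had 1 symbol and stood for 5680 genes. The filter looks at signal alone. The ages were compared, 15-month minus 2-month, with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend and robust variance), two-sided, with Benjamini-Hochberg adjustment and a false discovery rate of 0.05. Intervals are at 95%. Signals are given as mean ± SD over mice, and log2 changes as estimate ± SE of the limma fit.

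Gene lists were tested with camera of limma, a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 30 lists, with 1 probe set per gene, the one of highest mean. Of the 31 lists 1 had fewer than 5 genes bright enough and was not tested. The lists are fixed by textbook knowledge and some genes stand on more than 1 list. They cover microglia and macrophages, complement, MHC class I, interferon response, astrocytes, oligodendrocytes and their progenitors, endothelium and pericytes, choroid plexus, meninges and fibroblasts, red blood cells, and neighbouring thalamus, habenula and striatum. They also cover collagens, immature neurons, cell cycle, glutamate receptors, synaptic vesicles, the GABA system, potassium and calcium channels, hippocampal fields, immediate-early genes, the circadian clock, glucocorticoid-responsive genes, oxidative phosphorylation, antioxidant genes, the proteasome, chaperones, cholesterol synthesis, the lysosome, ribosomal proteins and RNA splicing. Calls were repeated with a correlation estimated per list and with fry, which tests whether a set's genes move one way and compares them with no other genes.

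Genes to be named were fixed by a rule: up to 10 of the largest changes in each direction among genes past the threshold, the 3 members of lowest p of each called list, the member of lowest p of any other list if it passed, and Gfap, C4b, B2m, Dcx, Ttr, Mbp, Fos and Hba-a1 whatever their result. Each gene stood for its brightest probe set with 1 symbol, and C4b had no probe set of its own. The design, the lists, the rule and the alternatives, except those said below to be added, were fixed before the data were examined.

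Values of arrays and lists between the ages were compared with exact two-sided permutation tests over all 817190 regroupings, and correlations between mice with 100000 permutations, with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 in Python 3.11.15. Figures were drawn with matplotlib 3.10.9. The limma test was tested on simulated data with the 7453 probe sets, of which 200 were shifted. It called 18% of those shifted by 0.25 on the log2 scale, 80% at 0.5, 88% at 0.75 and 98% at 1, and 1 of 7253 unshifted ones. Both of 2 lists shifted by 0.2 were called and 0 of 28 others. The simulated genes varied independently of one another, so this does not show how often camera calls lists of correlated genes by chance.

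The alternatives tried were pseudocounts of 1 and 64, quantile normalisation, median scaling, no filter and a filter at the 60th percentile, a fit without trend and robust variance, array weights (statmod 1.5.0), the choroid plexus score as a covariate, an exact Mann-Whitney test, leaving out each array in turn and the 2 farthest arrays together. For lists they were an estimated correlation, ranks, fry and the mean of a gene's probe sets. Added after the data were seen were the 25th percentile of each array as a covariate and leaving out the 4 arrays of lowest 99th percentile.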

Results

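Gene expression was measured in the whole hippocampus of 23 male C57BL/6JNIA mice, 14 of 15 months and 9 of 2 months, with 1 array per mouse. All of the mice had been trained in the Morris water maze, a test of spatial memory that depends on the hippocampus, before the tissue was taken. The comparison of the ages asks which hippocampal transcripts differ between young and middle-aged mice. The values were MAS5 signals on a linear scale, and 7453 of 12422 non-control probe sets were bright enough to be tested. The median signal of an array lay between 155 and 188, and pairs of arrays correlated at 0.935 to 0.983 on the log2 scale. None of 9 array measures passed an exact permutation test between the ages, the lowest p being 0.136. The array of 15-month replicate 13 stood apart, with a median correlation of 0.944 with the other arrays and a 25th percentile of 53.6, against 30.3 to 41.9 on the other arrays. On 4 arrays, 15-month replicates 3 and 12 and 2-month replicates 7 and 8, the 99th percentile lay between 6622 and 6966, below that of the other arrays. The number of arrays limits the precision of every value.

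At 15 months the hippocampus held more transcript of microglial, complement and antigen presentation genes, and of genes induced by glucocorticoids, than at 2 months. Ctss, the lysosomal protease cathepsin S of microglia, rose 1.41-fold (95% interval 1.30 to 1.53), from a signal of 1725 ± 153 (SD, n = 9) to 2443 ± 219 (SD, n = 14). Sgk1, a kinase induced by glucocorticoids, rose 1.96-fold (95% interval 1.53 to 2.52), from 1028 ± 160 to 2138 ± 770. Ighm, the heavy chain of immunoglobulin M, rose 1.66-fold, from 408 ± 57.5 to 692 ± 131. The fall with the lowest p was that of Tubg1, a gamma-tubulin gene, from 1328 ± 126 to 958 ± 127.

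In the limma test 28 probe sets changed at a false discovery rate of 0.05, of which 25 were higher and 3 lower at 15 months. Their log2 changes were between 0.23 and 1.05 in size. At an unadjusted p under 0.05 the split was more even, with 439 probe sets higher and 485 lower, together 12.4% of those tested. The median log2 change of all tested probe sets was -0.02. Of the 28, 25 matched 1 gene each, 2 matched several genes and 1 had no gene symbol. The probe set with the lowest p was 1 of those matched to several genes. It had 2 gene symbols, so no gene is named for it, and its signal rose from 867 ± 129 to 1809 ± 230. Its log2 change was 1.05 ± 0.08 (SE; adjusted p = 1.39e-09), higher in 14 of 14 mice than the 2-month mean, and the other such probe set had one of 0.90 (adjusted p = 0.0128), also in 14 of 14. The count of lower probe sets was 7 without 15-month replicate 3 and 5 without 15-month replicate 9, 10 or 12. With the 25th percentile of each array in the limma model, chosen after the data were seen, 60 probe sets changed, 39 higher and 21 lower, with all of the 28 among them.

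**Figure D1:**
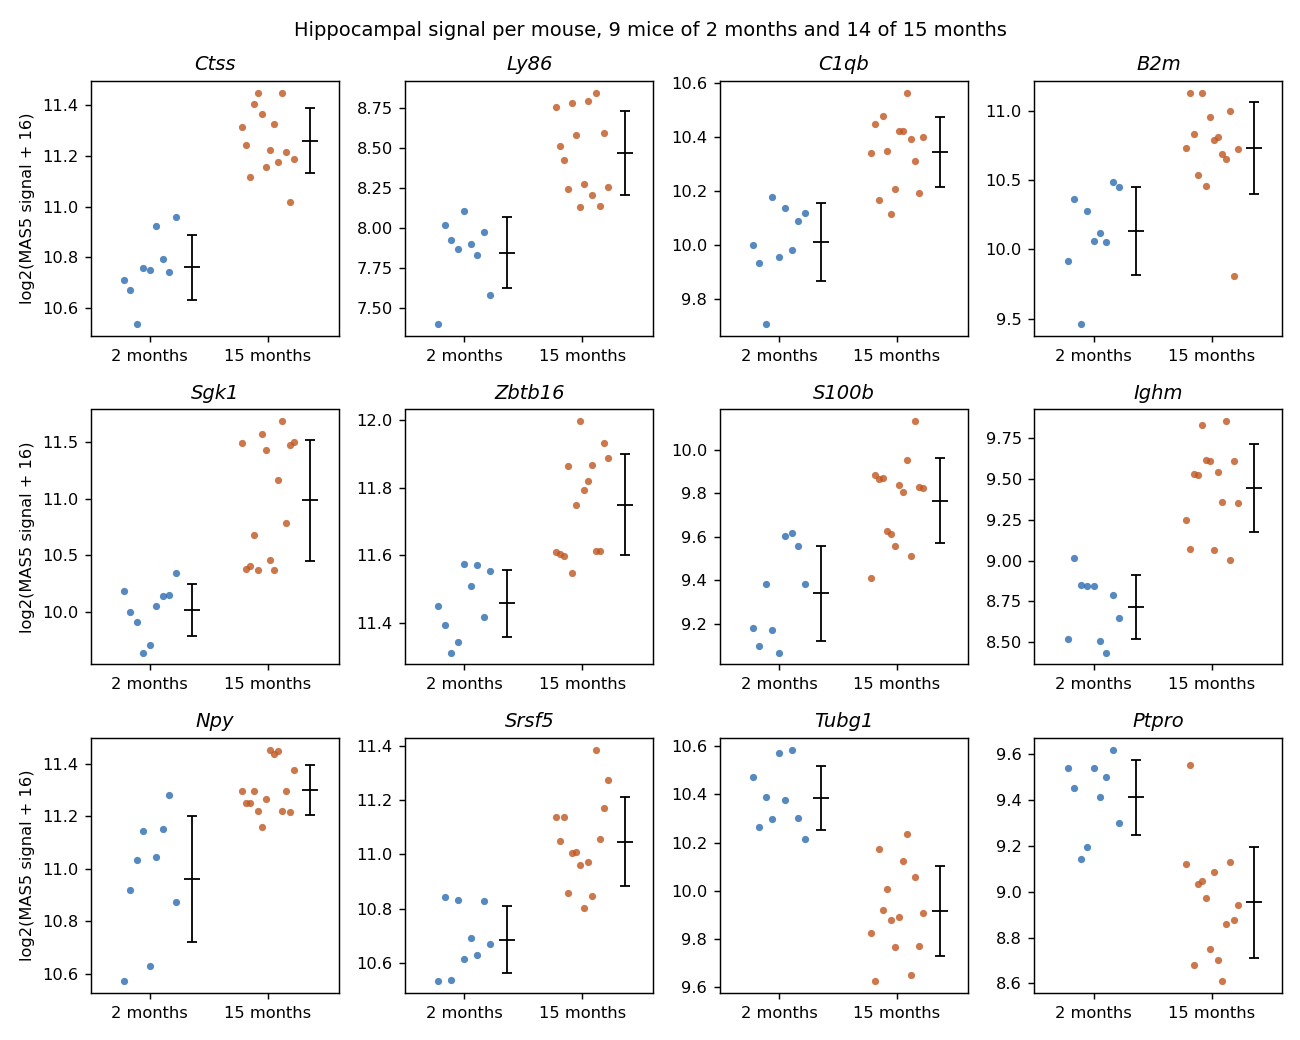
Signal of 12 genes in each mouse, as log2(MAS5 signal + 16) on the vertical axis, with 9 mice of 2 months in blue and 14 of 15 months in orange; each point is 1 mouse, and the bars beside the points give the mean ± SD. The 15-month mice lie between 11.02 and 11.45 for Ctss, above the highest 2-month mouse at 10.96, and spread from 10.37 to 11.69 for Sgk1.

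Beyond these, the largest rises among genes represented by their brightest probe set were those of Rin2, Ly86, Pglyrp1, Anxa2, B2m, Slc2a1 and Mpeg1. Rin2, which encodes a Rab5 effector that also interacts with Ras, had a log2 change of 0.69 ± 0.13 (SE; adjusted p = 0.00889). Pglyrp1, a peptidoglycan recognition protein of innate immunity, had one of 0.61 ± 0.11 (adjusted p = 0.00494), and Anxa2, a calcium-dependent membrane-binding annexin, one of 0.61 ± 0.12 (adjusted p = 0.0128, lost with the Mann-Whitney test at 0.0680 and without the 4 arrays of lowest 99th percentile, a setting chosen after the data were seen, at 0.0697). Slc2a1, the glucose transporter of the blood-brain barrier, rose by 0.55 ± 0.12 (adjusted p = 0.0220), a call lost without 2-month replicate 2, 3, 4 or 5 (adjusted p up to 0.0649), without the 2 farthest arrays (0.0541) and with the Mann-Whitney test (0.0814). Each of these 4 genes was above the 2-month mean in 14 of 14 mice of 15 months. Ighm had a log2 change of 0.73 ± 0.10 (adjusted p = 2.08e-04) in 14 of 14 mice, from a probe set whose suffix marks probes that can be shared with related sequences, as does that of Cuta. Second probe sets of Ighm (log2 change 0.39, adjusted p = 0.145) and of Pglyrp1 (0.56, adjusted p = 0.0830) did not pass the test. The 3 falls were those of Tubg1 (log2 change -0.47 ± 0.07, adjusted p = 0.00101), Ptpro, a receptor tyrosine phosphatase (-0.46 ± 0.09, adjusted p = 0.0128, but 0.0712 without the 4 arrays), and Cuta, a homologue of a bacterial copper tolerance gene (-0.27 ± 0.06, adjusted p = 0.0234). The call of Cuta was lost without 2-month replicate 1, 2, 3 or 7 (adjusted p 0.0527 to 0.0722) and without the 2 farthest arrays (0.0690). For these genes 0, 1 and 0 of the 14 mice of 15 months were above the 2-month mean. The transcription factor gene Tfcp2l1 (0.71), the non-coding RNA Gas5 (0.23), the phosphatidate phosphatase gene Lpin1 (0.39), the calcium-binding protein gene S100a6 (0.40) and Smad1 of bone morphogenetic protein signalling (0.45) also rose, each in 14 of 14 mice. They fall outside the rule for naming genes and were chosen after their values were seen. Other probe sets did not pass for Tfcp2l1 (0.02, adjusted p = 0.957), Gas5 (adjusted p = 0.317) and Smad1 (0.23, adjusted p = 0.147). For Tfcp2l1 the brightest probe set was thus not called.

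Microglial, complement and antigen presentation genes were higher as groups at 15 months. Of 19 microglia and macrophage markers 3 rose, Ctss, Ly86 and Mpeg1, and 5 rose and 1 fell when adjusted over the list alone (camera adjusted p = 7.73e-05). Ly86, a partner of a Toll-like receptor homologue, had a log2 change of 0.62 ± 0.11 (adjusted p = 0.00397), and Mpeg1, a pore-forming protein of macrophages, one of 0.55 ± 0.10 (adjusted p = 0.00494). Other markers of the list stayed near the 2-month level, such as Csf1r (log2 change 0.01) and Cx3cr1 (0.01), and the 1 that fell over the list alone was Coro1a (-0.20), genes chosen after their values were seen. Of 10 complement genes 2 rose, and 3 when adjusted over the list alone (camera adjusted p = 1.28e-04). These were the chains of C1q, the first component of the classical pathway, with log2 changes of 0.33 ± 0.06 for C1qb (adjusted p = 0.00695), 0.31 ± 0.07 for C1qc (adjusted p = 0.0223, lost without 2-month replicate 2 or 3 at 0.0546 and 0.0649 and with the Mann-Whitney test at 0.0536) and 0.21 ± 0.07 for C1qa (adjusted p = 0.162, passing over the list alone). A dimmer probe set of C1qb had a log2 change of 0.00. Of 12 genes of MHC class I and antigen processing B2m, the light chain of MHC class I molecules, rose by 0.60 ± 0.13 (adjusted p = 0.0234) in 13 of 14 mice, and 5 rose when adjusted over the list alone (camera adjusted p = 7.73e-05). The call of B2m was lost without 2-month replicate 1, 3 or 7 (adjusted p 0.0527 to 0.0695), with the Mann-Whitney test (0.0536) and without the 4 arrays (0.0664). The class I genes H2-Q4 (0.67 ± 0.20, adjusted p = 0.149) and H2-M3 (0.54 ± 0.14, adjusted p = 0.103, but 0.0440 without 2-month replicate 6) did not pass over all probe sets, and probe sets of this gene family can share probes. The list of meninges and fibroblasts was also called higher, with a median of 0.20, a call lost with an estimated correlation (adjusted p = 0.789) and with fry (0.724). With meninges and endothelium scores in the model, chosen after the list results were seen, the mean log2 shift of the MHC class I list was 0.22, against 0.24 without them. These 3 immune groups kept their calls with an estimated correlation, with adjusted p = 0.00445, 0.00445 and 0.0290. In contrast, none of 14 interferon response genes passed, also when adjusted over the list alone, with a median log2 change of 0.06 (camera adjusted p = 0.508). That list holds 52 genes, and those not among the 14 were not tested, so a change in them is not excluded.

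Glucocorticoid-responsive genes were higher at 15 months and differed widely among the mice of that age. Of 25 members 3 rose, and 9 when adjusted over the list alone (camera adjusted p = 3.28e-10, or adjusted p = 0.0311 with an estimated correlation). Sgk1 had a log2 change of 0.97 ± 0.17 (adjusted p = 0.00613), Rhob, a small GTPase, one of 0.30 ± 0.07 (adjusted p = 0.0330), and Zbtb16, a zinc finger transcription factor, one of 0.29 ± 0.06 (adjusted p = 0.0128), each above the 2-month mean in 14 of 14 mice. The probe set of Zbtb16 can share probes with related sequences. The call of Rhob was lost without 15-month replicate 2, 4, 8, 10 or 14 or 2-month replicate 1, 2, 3, 4 or 5 (adjusted p 0.0507 to 0.0965) and in 4 other settings (0.0511 to 0.0726). Fkbp5, a co-chaperone of the glucocorticoid receptor chosen after its value was seen, had a log2 change of 0.25 (adjusted p = 0.285), and 21 of the 25 members had changes above 0. The SD of the list mean between mice was 0.19 on the log2 scale at 15 months and 0.05 at 2 months. In 15-month replicates 1, 6, 7, 10, 11, 13 and 14 the list mean was 10.01 to 10.18, a grouping made after the values were seen. The other 15-month mice were at 9.70 to 9.83, close to the 2-month mice at 9.56 to 9.75, and so carried little of the rise. Sgk1 was at 2282.5 to 3276.8 in the named replicates and at 1307.1 to 1744 in the other 15-month mice. The list of immediate-early genes, several of which neuronal activity induces, was not called (median log2 change 0.00, camera adjusted p = 0.907, with 0 risen and 1 fallen over the list alone). Fos was at 299 ± 133 at 15 months and 286 ± 95.2 at 2 months (adjusted p = 0.990).

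**Figure D2:**
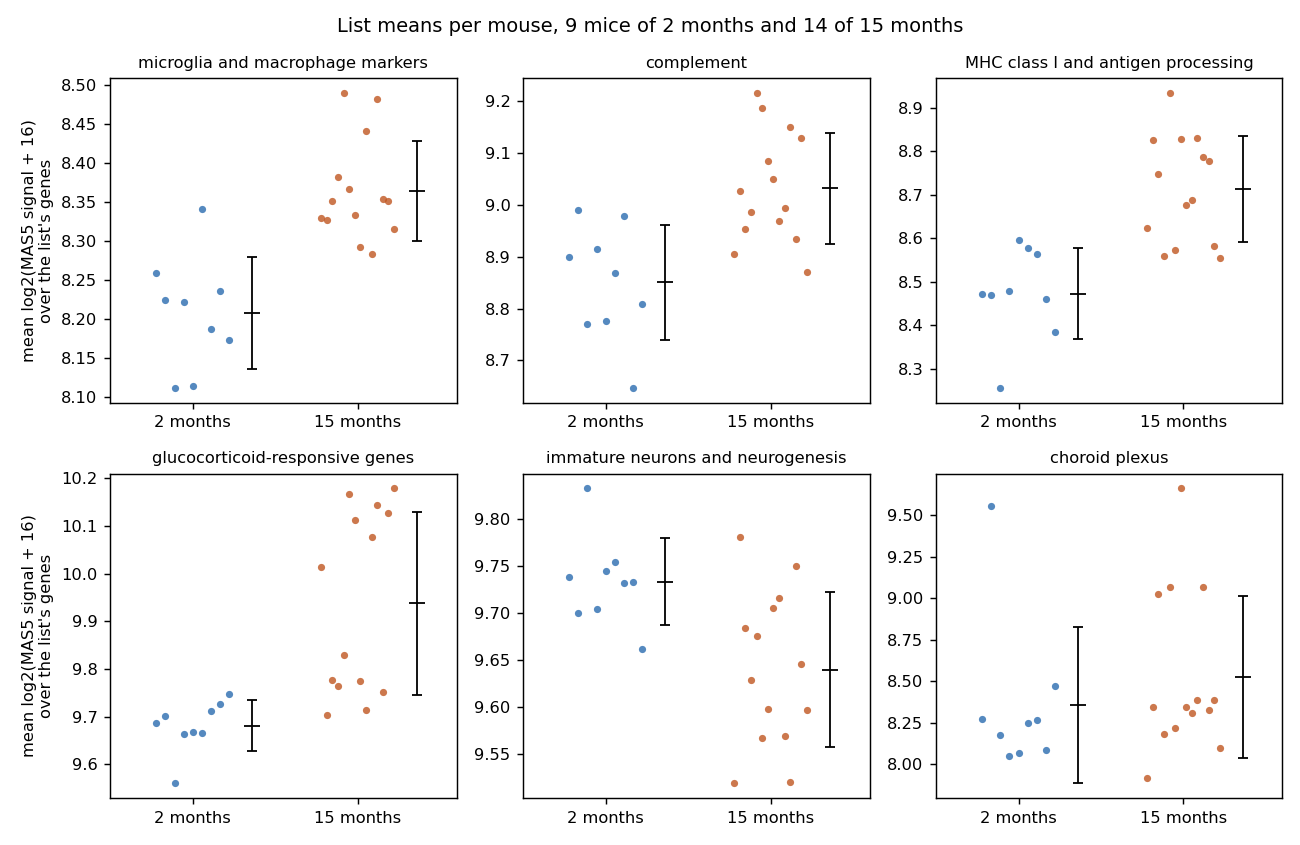
Mean of log2(MAS5 signal + 16) over the tested genes of 6 lists in each mouse, with 9 mice of 2 months in blue and 14 of 15 months in orange; each point is 1 mouse, and the bars beside the points give the mean ± SD. For the glucocorticoid-responsive list the 15-month mice spread from 9.70 to 10.18 and the 2-month mice from 9.56 to 9.75, and for the choroid plexus list both ages hold mice far above the rest, up to 9.66 and 9.56.

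Splicing, astrocyte and lysosome genes were also higher as groups, with calls that were lost with an estimated correlation. Of 99 other splits of the mice 84 also called at least 1 list, with a median of 3. Of 46 genes of RNA splicing and binding Srsf5, a splicing factor, rose by 0.36 ± 0.06 on the log2 scale (adjusted p = 0.00512), and 5 rose when adjusted over the list alone. The camera adjusted p of this list was 7.73e-05, with adjusted p = 0.120 with an estimated correlation. Its members Pnn, a nuclear speckle protein gene (0.45 ± 0.12, adjusted p = 0.117, but 0.0246 without 15-month replicate 10), and Hnrnpa1, an RNA-binding protein gene (0.36 ± 0.10, adjusted p = 0.120, but 0.0351 with the 25th percentile covariate, the range over all settings being 0.0351 to 0.225), did not pass over all probe sets. Of 27 astrocyte markers S100b, a calcium-binding protein, rose by 0.43 ± 0.09 (adjusted p = 0.0128, but 0.0536 with the Mann-Whitney test), and 4 rose when adjusted over the list alone. The camera adjusted p of the astrocyte list was 0.0139, or 0.0615 without 15-month replicate 6, 0.0535 without the 2 farthest arrays and 0.0795 on ranks, with adjusted p = 0.108 with an estimated correlation. Gfap, the astrocyte intermediate filament, measured by a probe set that can share probes with related sequences, was at 1820 ± 341 at 15 months and 1329 ± 262 at 2 months, a log2 difference of 0.45 ± 0.11 in 13 of 14 mice that did not pass (adjusted p = 0.0851). It passed without 15-month replicate 3 or 12 or 2-month replicate 6 or 7 (adjusted p 0.0174 to 0.0464). A dimmer probe set of Gfap had a log2 change of 0.24 (adjusted p = 0.255). Htra1, a secreted protease, had a difference of 0.34 ± 0.08 (adjusted p = 0.0613), which passed without 15-month replicate 3, 8 or 9 or 2-month replicate 1 (adjusted p 0.0249 to 0.0467), with the 60th-percentile filter (0.0451) and with the 25th percentile covariate (0.0406). Of 41 lysosome genes Ctss, also a microglia marker, rose, and 2 rose when adjusted over the list alone. The camera adjusted p of this list was 0.0391, with adjusted p = 0.129 with an estimated correlation. Its call was lost without 15-month replicate 2, 5, 6, 7 or 10 or 2-month replicate 3, 7, 8 or 9 (adjusted p 0.0535 to 0.0816). Ctsz, another cathepsin, had a log2 change of 0.46 ± 0.11 (adjusted p = 0.0508, passing at 0.0114 to 0.0463 without 15-month replicate 6 or 13 or 2-month replicate 7, 8 or 9 and at 0.0215 to 0.0475 in 7 of 12 other settings), and Laptm4a, a lysosomal membrane protein, one of 0.27 ± 0.09 (adjusted p = 0.196).

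Genes of immature neurons and of potassium and calcium channels were lower as groups at 15 months, with calls that were lost with an estimated correlation and no single member past the test. Of 37 genes of immature neurons and neurogenesis 29 had log2 changes below 0, with a median of -0.08 (camera adjusted p = 0.0139, or adjusted p = 0.129 with an estimated correlation and 0.0647 with the 60th-percentile filter). None passed when adjusted over the list alone. Its members of lowest p were the neuronal RNA-binding gene Elavl4 (-0.35 ± 0.11, adjusted p = 0.168) and the transcription factors Sox11 (-0.48 ± 0.18, adjusted p = 0.255) and Sox4 (-0.28 ± 0.12, adjusted p = 0.324). Dcx, a microtubule protein of migrating neuroblasts, was at 176 ± 22.4 at 15 months and 208 ± 45.7 at 2 months (adjusted p = 0.434). Of 32 channel genes 24 had changes below 0, with a median of -0.10 (camera adjusted p = 0.0271, or adjusted p = 0.277 with an estimated correlation), and none passed when adjusted over the list alone. The channel call was lost without 15-month replicate 2 or 7 or 2-month replicate 4 or 8 (adjusted p 0.0536 to 0.0937), with the 60th-percentile filter (0.351), the choroid plexus covariate (0.0505), fry (0.0528) and the mean of probe sets (0.0561). Kcnj11, a subunit of ATP-sensitive potassium channels, had a log2 change of -0.60 ± 0.24 (adjusted p = 0.295), and Cacna1a, a calcium channel subunit, one of -0.24 ± 0.10 (adjusted p = 0.317). Kcnj9 had a change of -0.32 ± 0.12 (adjusted p = 0.285) in its brightest probe set and of 0.08 in another.

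**Figure D3:**
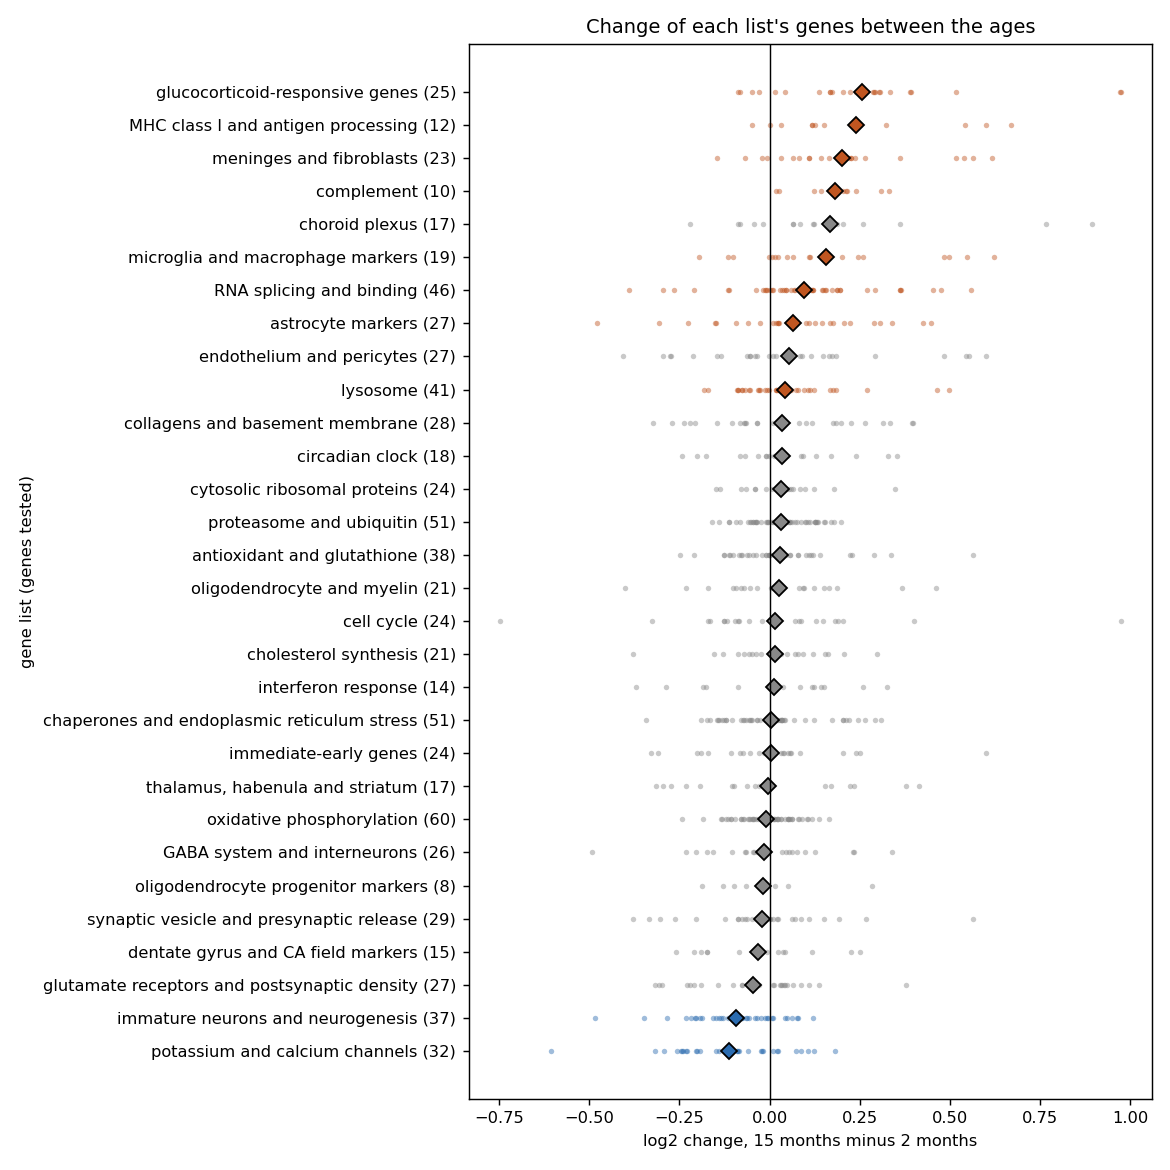
Log2 change from 2 to 15 months of the tested genes of 30 fixed lists, with the number of genes in brackets; small points are genes, diamonds are the list means, and colour marks lists called higher (orange), called lower (blue) or not called (grey) by camera. The list means run from -0.11 for potassium and calcium channels to 0.26 for glucocorticoid-responsive genes.

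Choroid plexus genes varied strongly between mice of both ages, with an SD of the list mean of 0.49 on the log2 scale at 15 months and 0.47 at 2 months, and meningeal genes were higher as a group at 15 months, a call lost with an estimated correlation. Of 23 genes of meninges and fibroblasts none passed, also when adjusted over the list alone, while the list was called higher with a median of 0.20 (camera adjusted p = 0.00425, or adjusted p = 0.789 with an estimated correlation, 0.724 with fry and 0.129 with the 60th-percentile filter). Its members of lowest p were the growth factor gene Bmp6 (0.62 ± 0.22, adjusted p = 0.244), the ferroxidase gene Cp (0.56 ± 0.22, adjusted p = 0.282) and the matrix protein gene Mgp, whose probe set can also share probes (0.54 ± 0.24, adjusted p = 0.354), and its estimated correlation between genes was 0.479. The 17 genes of the choroid plexus list had a median of 0.12, none passed, also when adjusted over the list alone, and the list was not called (mean 0.17, camera adjusted p = 0.203). Without 2-month replicate 2 it was called (mean 0.32, adjusted p = 7.38e-04), and without 15-month replicate 7 the mean was 0.08 (adjusted p = 0.790), the range of adjusted p over all settings being 7.38e-04 to 0.873. Ttr, the transthyretin gene and the most prominent transcript of the choroid plexus, was at 1802 ± 2924 at 15 months and 1293 ± 2969 at 2 months (log2 change 0.89, adjusted p = 0.729). The 2-month mean rested on replicate 2, at 9134 against 68.9 to 1377 in the others, and the log2 change of Ttr was 1.51 without that mouse and 0.58 without 15-month replicate 7. The haemoglobin gene Hba-a1 was at 3204 ± 720 and 2909 ± 562 (adjusted p = 0.681), and the red blood cell list had only 3 genes bright enough and was not tested. The myelin gene Mbp was at 5376 ± 803 and 5334 ± 1227 (adjusted p = 0.927), and another of its probe sets had a log2 change of -0.10.

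The other lists were not called. Of 27 endothelium and pericyte genes Slc2a1 rose, and 3 rose and 1 fell when adjusted over the list alone (median 0.01, camera adjusted p = 0.508). Of 26 genes of the GABA system and interneurons Npy, a neuropeptide of interneurons, rose by 0.34 ± 0.07 (adjusted p = 0.0159), from 2003 ± 322 to 2511 ± 169, and was the only 1 over the list alone (median -0.02, camera adjusted p = 0.725). In the remaining lists no gene passed over all probe sets. None passed over the list alone either, except where a count is given. The proteasome and ubiquitin list had a median of 0.04 and a camera adjusted p of 0.0549, and was called without 15-month replicate 3, 9, 10 or 13 or 2-month replicate 4, 5, 7 or 8 (0.0174 to 0.0496) and in 6 of 16 other settings (0.0156 to 0.0435). Cytosolic ribosomal proteins gave 0.03 and 0.249, and were called without 15-month replicate 3 (adjusted p = 0.0383). The median changes and camera adjusted p were 0.01 and 0.508 for the circadian clock, -0.00 and 0.508 for antioxidant and glutathione genes, and 0.02 and 0.551 for collagens and basement membrane. They were 0.01 and 0.551 for both oligodendrocyte and myelin and cholesterol synthesis genes, with 1 risen over the list alone in each, and -0.05 and 0.875 for oligodendrocyte progenitor markers. Neuronal lists gave -0.03 and 0.629 for glutamate receptors and postsynaptic density, -0.03 and 0.664 for dentate gyrus and CA field markers, and -0.02 and 0.839 for synaptic vesicle and presynaptic release, with 1 fallen over the list alone in the last. Markers of thalamus, habenula and striatum, tissue next to the dissection, gave -0.04 and 0.839, with 2 risen over the list alone. The cell cycle list gave -0.01 and 0.907, with 1 fallen over the list alone, oxidative phosphorylation -0.00 and 0.907, and chaperones and endoplasmic reticulum stress -0.01 and 0.907. The median, mean and test differed in sign for 7 uncalled lists, those of the GABA system, thalamus, cell cycle, antioxidant, immediate-early, oxidative phosphorylation and chaperone genes.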

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

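The test of whether the microglia markers rise alike and those with meninges and endothelium scores were chosen only after the result was seen. In the 9 mice of 2 months, 81 values were searched for a mouse far from the rest, by the gap to its nearest neighbour divided by the whole range, and 7 were found. Chance marks about 1 in 20 values in this way, here 4.05. The 14 mice of 15 months were not searched in this way, since the critical values used cover smaller groups only.

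In 2-month replicate 3 the log2 signals of H2-Q4 (6.08, the other mice 7.37 to 8.28, ratio 0.585), C1qa (10.23, the others 10.62 to 10.90, ratio 0.573) and Kcnj9 (7.94, the others 8.46 to 8.96, ratio 0.509) were far below the rest. The mean of the glucocorticoid-responsive list was also lowest in that mouse (9.56, the others 9.66 to 9.75, ratio 0.547). In 2-month replicate 2 Cacna1a was lowest (8.34, the others 8.75 to 9.11, ratio 0.530) and the choroid plexus list highest (9.56, the others 8.05 to 8.47, ratio 0.718). In 2-month replicate 1 the list of RNA splicing and binding was lowest (9.66, the others 9.79 to 9.92, ratio 0.522).

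The 28 changed probe sets are more than chance gives among 100 splits of the 23 arrays into 14 and 9: only the real 1 of 100 reached 28, and the highest of the others was 1. The number of called lists, 10 in the real split, stood out less. Of the 100 splits 3, the real one included, gave as many, which is under the share of 0.05 fixed beforehand. The highest of the others gave 11, so chance can reach this count too. The count says nothing of single lists: 84 of the 99 other splits called at least 1 list, with a median of 3, so the preset correlation calls lists by chance too.

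The rise of the microglia, complement and MHC class I lists could come from choroid plexus, meningeal or vessel tissue in some dissections, from the background and dynamic range of the arrays, or from a larger share of microglia. With the choroid plexus score in the model the mean log2 shift of their genes was 0.179 (95% interval 0.124 to 0.234), against 0.187 without it, and with the 25th and 99th percentiles of each array it was 0.192 (0.125 to 0.259). With meninges and endothelium scores it was 0.183 (0.129 to 0.238), and 0.218 (0.128 to 0.307) for the MHC class I list alone, against 0.240. All 3 lists kept their calls in each of these models. This argues against each of these tissues and array measures as the whole cause, as far as the scores and percentiles measure them. A larger share of microglia alone would move their markers alike only if background and other cells added nothing to each signal, which was not measured. The 19 markers of the microglia list spread from -0.35 to 0.46 around their mean, with a permutation p of 1e-05, the smallest that 100000 permutations can give. The markers thus did not change alike, but this cannot decide whether a larger share was the whole cause. A share of microglia stays open for all 3 lists, as does, as a hypothesis found on the same data, a difference of age in expression.

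The rise of the glucocorticoid-responsive list could come from the time of day at killing, which the sources used here do not give, or from the share of astrocytes and vessels. With a clock phase score in the model the mean log2 shift was 0.221 (95% interval 0.092 to 0.350), against 0.257 without it, and with astrocyte and endothelium scores it was 0.253 (0.0995 to 0.407), the list keeping its call in both. The second fit argues against the share of astrocytes and vessels as the whole cause, as far as those scores measure it. The clock score only stands in for the time of day. Among the 15-month mice with the higher list means it was 0.26 to 1.08 in replicates 1, 6, 7, 10, 11 and 14 and -0.12 in replicate 13. Among the other 15-month mice it was -1.32 to -0.24 in replicates 2, 3, 4, 9 and 12. In replicates 5 and 8 of these it was 0.67 and 1.09. The score was thus higher in most mice with the higher list means, a difference that was not tested. Such a score cannot take up all that goes with the time of day, so the time of killing stays open. Stress before killing that differed between mice was not tested and stays open, as does a difference of age in the response.

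The rise of Ighm could come from blood or choroid plexus in the tissue. With Hba-a1 and Hbb-b2 in the model its log2 change was 0.688 (95% interval 0.440 to 0.936), and with the choroid plexus score 0.698 (0.502 to 0.893), against 0.729 without either. The second fit argues against choroid plexus tissue as the whole cause, as far as its score measures it. The first argues only against a larger amount of blood as the whole cause, as far as haemoglobin transcripts measure it. Hba-a1 was at 3204 ± 720 at 15 months and 2909 ± 562 at 2 months. Haemoglobin does not show how much Ighm transcript the blood carried, so blood richer in that transcript stays open. A difference of age, immunoglobulin-producing cells in the tissue and probes that bind related sequences were not tested and stay open.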

How the results depend on the processing

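The settings with the 25th percentile covariate and without the 4 arrays of lowest 99th percentile were chosen after the data were seen. The count of 28 changed probe sets was 26 to 35 in 12 other settings and 60 (39 higher, 21 lower) with the 25th percentile covariate. Of the 28 calls, 22 were kept by the exact Mann-Whitney test, 24 without the 2 farthest arrays, 23 without the 4 arrays, and 27 or 28 in the other settings that tested all of them. The 60th-percentile filter tested 24 of them and kept all 24. The count of lower probe sets, 3, was 6 with the 60th-percentile filter, 5 with array weights and 8 with the Mann-Whitney test.

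Leaving out 1 array at a time gave 20 (without 2-month replicate 3) to 39 (without 15-month replicate 3) changed probe sets, 18 to 32 higher and 2 to 7 lower, with 7 lower without 15-month replicate 3 and 5 without 15-month replicate 9, 10 or 12. Lists called higher were 6 to 10, against 8, and lists called lower 1 or 2, with 1 when 15-month replicate 2 or 7 or 2-month replicate 4 or 8 was left out, each of which ended the channel call (adjusted p 0.0536 to 0.0937). The lists called higher were 5 with the 60th-percentile filter and 4 with an estimated correlation, and those called lower 0 in both and 1 with the choroid plexus covariate, with fry and with the mean of probe sets. The microglia, MHC class I, complement and glucocorticoid lists kept their calls in all settings run, with the adjusted p at most 0.0116, 0.0290, 0.0329 and 0.0311. The lysosome call was kept in 7 of 16 settings and 14 of 23 fits without 1 array, and the astrocyte call was lost without 15-month replicate 6 (0.0615), without the 2 farthest arrays (0.0535), on ranks (0.0795) and with an estimated correlation (0.108). Gfap passed in 4 fits without 1 array and without the 4 arrays (log2 change 0.62, adjusted p = 0.00254, the range over all settings being 0.00254 to 0.201). The Mann-Whitney test ended the calls of Anxa2, B2m, Slc2a1, C1qc and S100b (adjusted p 0.0536 to 0.0814), leaving out the 4 arrays those of Anxa2, B2m and Ptpro (0.0664 to 0.0712), and leaving out the 2 farthest arrays those of Slc2a1, Cuta and Rhob (0.0541 to 0.0690). Rhob was lost in 3 more (0.0511 to 0.0726). The proteasome list was called with median scaling, no filter, array weights, ranks and either set of arrays left out (0.0156 to 0.0435). The 60th-percentile filter ended the channel (0.351), meninges (0.129) and immature neuron calls (0.0647), and fry the channel (0.0528) and meninges calls (0.724). The complement and interferon lists and some named genes were too dim for a value with this filter.

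Directions turned only in uncalled results near 0. Fos was -0.0737 with array weights, -0.0712 without the 2 farthest arrays and -0.0815 to 0.0985 with 1 array left out. Mbp was -0.000644 without the 2 farthest arrays, -0.0390 without the 4 arrays and -0.0230 to 0.105 with 1 array left out. For lists the direction of the test turned, with the mean log2 change given: for the cell cycle with array weights (0.00129), fry (0.0156), the mean of probe sets (-0.0105), the 2 farthest arrays left out (0.0218) and the 4 arrays left out (-0.0333) and without 1 array (range of all such fits 0.000259 to 0.0287). For chaperones it turned with array weights (0.0115), the mean of probe sets (0.000434) and the 2 farthest arrays left out (0.0121), and without 1 array (-0.00689 to 0.0274). For immediate-early genes it turned with the 25th percentile covariate (0.0150), ranks (0.00422) and the 4 arrays left out (0.0289), and without 1 array (-0.0120 to 0.0267). For oxidative phosphorylation it turned with the 25th percentile covariate (-0.0157), fry (-0.00910) and quantile normalisation (-0.0186), and without 1 array (-0.0180 to 0.00155). It also turned for hippocampal field markers with the 4 arrays left out (-0.00186), for thalamus markers with fry (-0.00461), and for oligodendrocyte progenitors with the 2 farthest arrays left out (-0.00352) and without 1 array (-0.0371 to -0.00135). The cause of these changes was not tested. As detection calls were not used, the signal at which a dim probe set stands above background is unknown.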

Other observations

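The test of the spread of the glucocorticoid-responsive list was chosen only after the result was seen. Among the array's controls, which the main test leaves out, the 3-prime probe set for the transferrin receptor was lower at 15 months. It was at 166 ± 40.5 (SD, n = 14) against 236 ± 52.8 (n = 9), a log2 difference of -0.48 (exact permutation p = 0.00119, adjusted p = 0.00950 over the control probe sets tested), lower than the 2-month mean in all but 1 mouse. The 5-prime (34.1 ± 14.7 against 62.4 ± 12.2) and middle ones (18.4 ± 12.2 against 32.7 ± 20.8) were below the filter of the main test, at signals whose distance from background is unknown, so no difference is drawn from them. In the main test the brightest probe set of Tfrc, the same gene, had a log2 change of -0.41 that did not pass (limma adjusted p = 0.153), and another of -0.18. The 3-prime control probe set of pyruvate carboxylase was at 740 ± 92.5 against 861 ± 76.8 (log2 difference -0.22, exact permutation p = 0.00549, adjusted p = 0.0293), and the other pyruvate carboxylase sets did not pass. Those of actin and Gapdh did not pass either, the lowest exact permutation p among them being 0.334.

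The glucocorticoid-responsive list varied more between the mice of 15 months, with an SD of 0.19 against 0.05 on the log2 scale, a ratio of 3.57. The test compared the mice's distances from the median of their own age, on average 0.179 at 15 months and 0.0366 at 2 months. Over all regroupings of these distances the permutation p was 4.89e-06 (adjusted p = 1.47e-04 over 30 lists). It is approximate, since the medians came from the same mice. No other list passed this test, the next being the GABA system with an SD ratio of 2.67 (adjusted p = 0.0808). Over all tested probe sets the SD was larger at 15 months in 58.2%, with a median log2 ratio of 0.11. Mice of 15 months may thus differ more from one another in this response, which is a hypothesis from the same data, and what sets them apart was not tested.

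Whether the rises of microglial and glucocorticoid-responsive genes occur in the same mice could not be told from 14 mice of 15 months: the scores correlated at r = -0.0486 (permutation p = 0.868) and Spearman's rho was 0.0418 (permutation p = 0.892), and r was -0.317 without the 2 mice farthest from the median. In 6 such relations tested none passed after adjustment. The lowest p was that of the choroid plexus score and Ighm at 15 months (r = 0.534, permutation p = 0.0472, adjusted p = 0.283; rho = 0.582, permutation p = 0.0310, adjusted p = 0.186), with r = 0.472 without the 2 mice farthest from the median.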
